A study of Mus musculus with 12 samples.

How the data were processed

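Kidney cortex RNA of 3 diabetic (STZ) and 3 menopausal/diabetic (VCD and STZ) mice was compared on 12 2-colour arrays. Per the labels, total RNA was extracted with spin columns 6 weeks after STZ, amplified as antisense RNA, turned into cDNA and coupled to Alexa Fluor 546 or Alexa Fluor 647, and each title names the animal of each dye. An array carries 31200 spots in 48 print blocks (4 by 12), each of 25 by 26 spots, and 15600 clones lie in 2 adjacent spots each. Per the file headers, the scanner files give the mean intensity of each spot and the median intensity of its local background in each channel, unscaled, together with a signal-to-noise score from the scanner software. Scanner software and settings are not given in the sources used here. The scanner's own normalized intensity and its score were not used in the comparisons, but its detection status in the Alexa Fluor 546 channel was counted. The authors also deposited a value table of log2 ratios per array, whose normalization is not given in the sources used here and whose column medians run from -0.0548 to 0.0911.

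The columns of the deposited log2 table did not match their own arrays. Over the brightest spots, 0 of 12 columns had their highest correlation with the scanner file of the same name. All 12 matched another array, each a different one and in the order of the slide numbers, with Spearman correlations across spots of -0.633 to -0.950, against sizes of 0.208 to 0.560 for the next array and values of -0.293 to 0.524 for their own. The negative sign puts Alexa Fluor 546 over 647. The scanner files were used, since the animal identifiers inside 11 of the 12 files match the titles. The array titled diabetic 2 and diabetic 3 carries another identifier for both dyes. The median residual SD was 0.180 with the titles and 0.189 with the order of the deposited columns, and 3 of 100 random orders of the arrays lay below the former and 29 below the latter. Turning the sign of an array in turn raised the residual for 7 of 12 arrays. The correlation of an array's ratios with those predicted from the other arrays, across genes, ran from -0.256 to 0.491. Among the 30 ordered pairs of animals that could predict an array, the titled pair ranked first for 0 of 12 arrays, with ranks of 2 to 30, and 6 arrays were better predicted by their titled pair turned round. The array of menopausal/diabetic 1 and diabetic 2 ranked 29 and its turned pair 2, and that of menopausal/diabetic 3 and 1 ranked 30 and its turned pair 1. Each animal level rests on the titles, which these ratios support weakly.

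Gene names come from the platform's probe table by probe number. Numbered in file order, clones of 1 gene had unlike brightness. All 384 orders of the slide's axes were compared on 2405 pairs of clones of 1 gene: counting from the bottom row gave a correlation of 0.362, the next order 0.0827 and the file order 0.0405. The 164 clones of ribosomal proteins had a mean brightness percentile of 86.9 in that order, 49.4 in file order and at most 56.6 in any other. The numbering from the bottom was therefore used. Of the spots, 18382 have 1 gene symbol, 508 several and 12310 none, and 18170 have a gene number found in the reference gene table, which updated the symbols. Spots with several genes or none were kept without a name. Clone coordinates are not given.

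Log ratios were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 and ratios were normalized by loess within each array, with no scaling between arrays. Across the arrays 23 spots without a background value were left out. The 2 spots of a clone were averaged, the 25% of clones with the lowest mean intensity were left out (3904 of 15600, leaving 11696), and the brightest clone stood for each gene. This left 5869 named genes and 4086 unnamed clones. Correlation between the 2 spots of a clone ran from 0.532 to 0.885 per array, across clones. Abnormal spots numbered 21 to 159 per array and saturated ones 0 to 10.

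Arrays of 1 animal are repeats of that animal, so the animal was the replicate. The 12 log ratios of each gene were fitted by least squares to 1 level per animal and a dye term, and the 6 levels were compared 3 against 3 by limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation of 3 against 3 animals cannot give a two-sided p under 0.1, so none is given. Differences among the 3 animals of a group were tested by the moderated F test on the 12 arrays, with a level per animal and the dye term; its error is that between arrays. Gene lists were fixed before the data were examined, 30 in number, covering nephron segments and other cell types, sex-biased and steroid genes, injury, matrix, inflammation, metabolism, stress, growth factors and the cell cycle. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, whose p tests whether the list's genes move 1 way on balance and whose mixed p tests change in either direction.

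The named genes were set by a rule written before the data were examined: 10 genes per direction, by size of change among those past the threshold with the groups apart, filled up with those of smallest p whose groups do not overlap; up to 4 members of smallest p of each list; and Mdk, Esr1, Kap, Ren1, Havcr1 and Lcn2. Genes without a symbol and predicted loci were skipped in the ranked part. Of the genes the rule named, 28 had more than 1 clone past the filter, and 20 of these had all clones on 1 side. The same held for 698 of 1316 named genes in all, and for 89 of the 141 at an unadjusted p under 0.05.

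On data simulated for this comparison, 5 sets of 9955 genes, the fit called 45.1% of genes changed by 0.5 log2. It called 89.3% of those changed by 1, 95.8% of those changed by 1.5 and 48 of 48775 unchanged genes. The simulated animals took the whole measured spread between animals, which already holds array error, and array error was then added again. They were thus noisier than the measured animals, and the shares called are not those at the measured errors. Camera gave an unadjusted p under 0.05 for 4 of 75 unchanged lists. The genes were drawn independently, so that share does not cover lists whose genes move together. In the measured data the estimated correlation was 0.564 for fatty acid oxidation and 0.541 for NRF2 targets. Alternatives set in advance were no background correction, median centring, scaling between arrays, 2 other filters on dim clones, spots with a mark left out, the 6 between-group arrays alone, separate channels, each animal and each array left out, a replicate block, a slide batch block, arrays as replicates, a variance trend, clones averaged or tested singly, and the other list tests. Alternatives chosen after seeing the data were print-tip loess, array weights, 10 arrays of the higher slide numbers, the set without 2 doubtful arrays, the set without the 2 arrays ranked last, the deposited log2 values with re-matched columns, and names by file order; the check of array orders was also chosen then. The deposited values under their own column names, set in advance, were not run because the columns match other arrays. Figures were drawn with matplotlib 3.10.9.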

Results

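Transcripts of kidney cortex were measured in 6 mice, 3 in each of 2 groups. Diabetic mice had received streptozotocin (STZ), a toxin of the insulin-making beta cells. Menopausal/diabetic mice had received VCD as well as STZ. VCD, vinylcyclohexene diepoxide, destroys the small follicles of the ovary and is used in mice to model a gradual menopause. RNA was taken 6 weeks after STZ. The RNA was amplified and hybridised in pairs of animals to 12 arrays of spotted cDNA clones, 6 pairing a menopausal/diabetic with a diabetic animal, 3 pairing diabetic animals and 3 pairing menopausal/diabetic animals. Each animal was on 4 arrays, 2 in each dye. Median signal over local background ran from 25.3 to 209 intensity units per array in the Alexa Fluor 546 channel and from 14.6 to 107 in the Alexa Fluor 647 channel. Between 30.5% and 57.4% of the spots of an array were called detected in the Alexa Fluor 546 channel. Detection counts of genes below use that channel alone, a clone counting if either of its spots was detected. The number of arrays and animals limits the precision. All levels below are log2 values relative to the mean of the 6 animals, and all changes are menopausal/diabetic minus diabetic.

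The comparison of the groups asks which kidney genes differ when VCD, the model of menopause, is added to diabetes. No group separates ovarian failure from other effects of VCD. No single gene passed the threshold. The 10 genes ranked first on the higher side included Ier3, an early-response gene that limits cell death, Clu, the secreted chaperone clusterin of injured tubules, and Slc3a2, the heavy chain of several amino acid transporters. The 10 ranked first on the lower side included 4 ribosomal protein genes and Acadm, the dehydrogenase that starts the oxidation of medium-chain fatty acids. Of 9955 genes and unnamed clones tested with limma on the 6 animals, 0 had an adjusted p under 0.05, the smallest adjusted p being 0.238. At an unadjusted p under 0.05 there were 833 (510 higher, 323 lower), where 498 would be expected from independent animal levels. Of the 833, 171 were printed in the 3 upper left print blocks of the slide, described below. Leaving out diabetic animal 2 gave 46 genes past the threshold, 44 of them higher, and leaving out any other animal gave 0. The size of single differences often rested on 1 animal: of the 112 genes named by rule, 55 fell below 0.5 times their difference or changed sign without diabetic animal 3, and 4 to 22 did so without any other animal. Of the 15 tested lists, the median of 11 did so without diabetic animal 3 and of 1 to 5 without any other. The groups did not overlap for 1423 genes, or 14.3%, against 10% by chance for independent levels. The array layout links the levels of different animals, so the 498 and the 10% are likely too low where array error dominates. A fit that took the 12 arrays as replicates, and so measured the groups against array error and not against other animals, gave 22 genes, 10 higher and 12 lower, with 968 at an unadjusted p under 0.05. The same kind of fit to the 6 between-group arrays gave 0, with 645 at an unadjusted p under 0.05.

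Ier3 had the largest difference among the ranked genes, 1.23 ± 0.16 (SE, 3 animals per group), a fold of 2.34 that did not pass the threshold (adjusted p 0.282). Its diabetic levels were -0.91, -0.33 and -0.60 and its menopausal/diabetic levels 0.39, 0.71 and 0.74. Clu had 0.54 ± 0.08. Pigs, a subunit of the complex that attaches lipid anchors to proteins, had 0.60 ± 0.09. Cfl1, the actin-severing cofilin, had 0.59 ± 0.09, and Cltc, the heavy chain of clathrin coats, had 0.44 ± 0.07. Efr3a, which holds a lipid kinase at the plasma membrane, had the smallest p of the ranked genes, with 0.48 ± 0.05. Slc3a2 had 0.40 ± 0.05. Fermt2, the integrin activator kindlin, had 0.44 ± 0.07, but its other clone lay on the other side. Rfpl4, a RING-finger protein best known from oocytes, had 0.48 ± 0.07 but was detected on 5 of the 12 arrays. Galnt2, which starts O-linked sugar chains in the Golgi, had 0.38 ± 0.06. The adjusted p of these 10 genes ran from 0.238 to 0.302. Each ± comes from the scatter of the animal levels, as moderated by eBayes, not from the residual SD between arrays. Ranking by p favours genes whose animals happen to lie close, so the SE of ranked genes is likely too small. That residual SD was 0.43 for Efr3a, 0.54 for Rfpl4 and 0.80 for Ier3. In the fit with arrays as replicates the unadjusted p was 0.0109 for Efr3a and 0.0301 for Rfpl4, and lower for the others. Of the 10, 8 were printed in the 3 upper left blocks of the 48 print blocks of the slide, where 31.3% of the tested clones had an unadjusted p under 0.05 against 7.04% elsewhere. Clu and Cltc were printed elsewhere. With 1 loess curve per print block, a choice made after seeing the data, the difference was 0.93 for Ier3, 0.54 for Clu, 0.29 for Pigs, 0.25 for Efr3a, 0.23 for Cfl1, 0.27 for Rfpl4, 0.19 for Galnt2, 0.18 for Fermt2, 0.14 for Cltc and 0.01 for Slc3a2. Without background correction it was 0.34 for Ier3, 0.25 for Clu and 0.10 for Rfpl4. Without diabetic animal 3 it was 0.28 for Efr3a, and with the re-matched deposited ratios it was 2.17 for Ier3 and -0.19 for Slc3a2. Sizes from these inputs, here and below, are not on 1 scale with the main values. The spread of all ratios was smaller without background correction and larger with the re-matched ratios.

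Among the 10 ranked lowest, 4 encode proteins of the cytosolic ribosome. Rps24 had a difference of -0.41 ± 0.08, Rps29 of -0.39 ± 0.05, Rps25 of -0.38 ± 0.06 and Rpl38 of -0.32 ± 0.06. With 1 animal left out Rpl38 ran from -0.51 to -0.17 (-0.17 without menopausal/diabetic animal 1, -0.22 without diabetic animal 3) and Rps24 from -0.58 to -0.26. Acadm had the largest difference of this side, -0.57 ± 0.08, with diabetic levels of 0.28, 0.29 and 0.29 and menopausal/diabetic levels of -0.35, -0.40 and -0.11. Mitochondria were also represented by Cox7c, a small subunit of cytochrome c oxidase, at -0.37 ± 0.05. Timm21, part of the inner-membrane import machinery, had -0.28 ± 0.06 and was detected on 5 of the 12 arrays. Krt8, a keratin of simple epithelia that injured tubules make, had -0.24 ± 0.04, but -0.07 without diabetic animal 3 and -0.03 with marked or saturated spots left out. Snx22, a sorting nexin of endosomes, and Thoc7, part of the complex that exports messenger RNA, both had -0.28. Print-tip loess gave -0.11 for Snx22 and -0.17 for Rps29, separate channels -0.01 for Acadm and -0.04 for Thoc7, and no background correction -0.07 for Timm21. The adjusted p of these 10 genes ran from 0.282 to 0.336, and none was printed in the upper left blocks. In the fit with arrays as replicates the unadjusted p was 0.108 for Krt8, 0.0875 for Timm21, 0.057 for Rps24 and 0.052 for Rpl38. The other genes of this side had a p under 0.05 in that fit. The residual SD between arrays was 0.29 for Rps29, 0.42 for Rpl38 and 0.39 for Krt8, so their ± is likely too small as well.

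**Figure D1:**
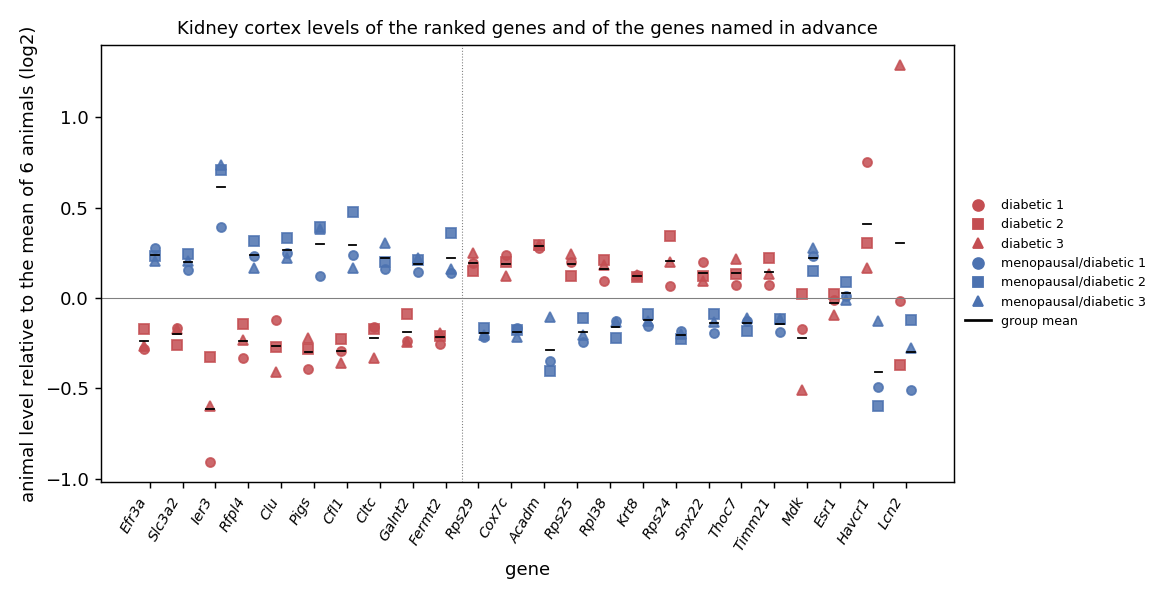
Level of each animal (log2, relative to the mean of 6 animals) for the 20 ranked genes, higher ones left of the dotted line, and for Mdk, Esr1, Havcr1 and Lcn2; red marks diabetic and blue menopausal/diabetic animals, marker shapes the animal, bars the group means. For Ier3 the diabetic animals lie between -0.91 and -0.33 and the menopausal/diabetic animals between 0.39 and 0.74, while Lcn2 stands at 1.29 in diabetic animal 3.

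**Figure D2:**
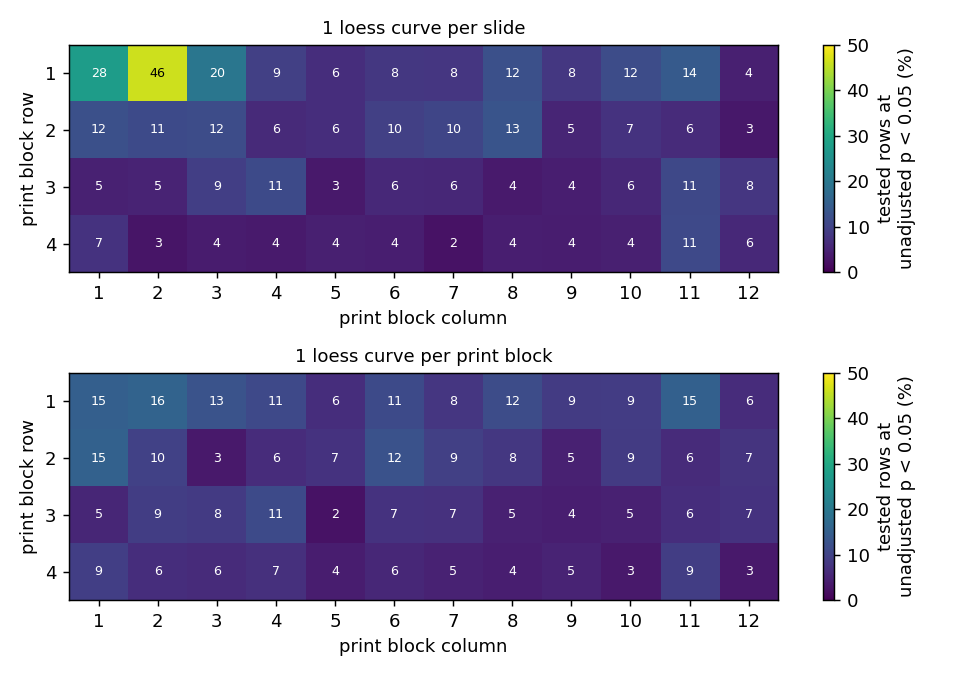
Percent of tested clones with an unadjusted p under 0.05 in each of the 48 print blocks of the slide, with 1 loess curve per slide (top) and 1 per print block (bottom). The 3 upper left blocks hold 31.3% such clones in the top map and 14.6% in the bottom one.

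Genes of tubular injury lay on both sides. Of the 10 measured, 0 passed over all genes and 4 passed adjusted over the list alone. Clu and Mdk were higher, Mdk being midkine, a heparin-binding growth factor of inflamed kidney. Krt8, whose size depended on diabetic animal 3, and Havcr1 were lower, Havcr1 being kidney injury molecule 1, a receptor that injured proximal tubules put on their surface. The difference was 0.44 ± 0.13 for Mdk (adjusted p 0.536, 0.23 without diabetic animal 3) and -0.82 ± 0.18 for Havcr1 (adjusted p 0.445), and the 3 menopausal/diabetic animals lay on 1 side of the 3 diabetic animals for both. Lcn2, the iron-carrier-binding lipocalin of injured distal tubules, had -0.60 ± 0.40 (adjusted p 0.724), and its level was 1.29 in diabetic animal 3 against -0.02 and -0.37 in the other diabetic animals. The list as a set had a median of -0.06 (-0.30 to 0.08 over the alternatives) and a camera p of 0.432 (estimated-correlation p 0.475). Fry, which here tests the list's own genes and not the list against other genes, gave a p of 0.252 for a move in 1 direction and an adjusted p of 0.00196 for change in either direction. Of the other genes named in advance, Esr1, the estrogen receptor alpha, had 0.06 ± 0.05 (adjusted p 0.836, -0.0081 without diabetic animal 3). Kap and Ren1 were not among the named probes.

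Fatty acid oxidation was the list with the smallest camera p, followed by endoplasmic reticulum stress and NRF2 targets. Of the 15 lists with at least 5 measured genes, camera called 0 at an adjusted p under 0.05, with 4 at an unadjusted p under 0.05. Camera with an estimated correlation called 0, with 0 at an unadjusted p under 0.05, and fry called 0, with 1. No camera call was there to hold or fail under the estimated correlation. Fry called 2 lists for change in either direction, tubular injury and immediate early genes (adjusted p 0.0101). Leaving out diabetic animal 1 gave 3 camera calls, fatty acid oxidation, NRF2 targets and extracellular matrix, and leaving out diabetic animal 3 gave 1. The 11 genes of fatty acid oxidation and PPAR-alpha targets, which burn fat in the proximal tubule, had a median of -0.19, with 9 of them lower (camera p 0.00974, adjusted p 0.134, estimated-correlation p 0.352). Adjusted over the list alone, 1 passed, Acadm. The others named were Acadl, the long-chain dehydrogenase, at -0.32, Acot2, a mitochondrial thioesterase, at -0.46 (-0.06 without diabetic animal 3), and Plin2, which coats lipid droplets, at -0.997 ± 0.68 (-0.13 without diabetic animal 3, where its level was 2.25). Without diabetic animal 3 the list's median was -0.0091, and without diabetic animal 1 its camera adjusted p was 0.00549.

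The 15 genes of oxidative stress and NRF2 targets had a median of -0.03 (camera p 0.0375, estimated-correlation p 0.490), and 0 passed adjusted over the list alone. Prdx1, a peroxidase of the cytosol, had -0.34 ± 0.08, Gstm1, a glutathione transferase, -0.30 ± 0.09, and Gpx1 and Sod1, which remove peroxide and superoxide, -0.18 (0.02 without diabetic animal 3) and -0.19. The list's median was 0.15 without diabetic animal 3 and -0.28 without diabetic animal 1 (camera adjusted p 0.00549). The list was called without background correction too (median -0.16, adjusted p 0.0172), and with the 6 between-group arrays (-0.03, 0.0272). Those 6 arrays gave the same median as all 12, so that call is no separate check of the difference. Of the 9 genes of lipid and sterol synthesis, 1 passed adjusted over the list alone, Elovl6, which lengthens fatty acids, at 0.53 ± 0.13, which was printed in the upper left blocks and shared its sign with 2 of its 4 clones, itself included. The list's median was 0.08 (0.03 without diabetic animal 3, camera p 0.0915, estimated-correlation p 0.154). Scd2, a desaturase, had 0.41 and Srebf1, the lipogenic regulator, 0.14 (0.07 and 0.03 without diabetic animal 3), and Hmgcs1, of cholesterol synthesis, had -0.15. Of the 16 oxidative phosphorylation genes, 9 were higher and 7 lower, with a median of 0.01 (-0.04 with 1 loess curve per print block, camera p 0.874, estimated-correlation p 0.874). Adjusted over the list alone 1 of them passed, Cox7a2, another oxidase subunit, at -0.31 ± 0.06, while Uqcrc2 of complex III had 0.29 (-0.12 with 1 loess curve per print block, being printed in the upper left blocks), Ndufv1 of complex I 0.19 and Cox4i1 -0.10. Among 4 genes of glucose handling the median was -0.01, with Txnip, which glucose induces, at -0.10, Pkm at 0.07 and Slc2a1 at 0.01.

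Of the 14 genes of endoplasmic reticulum stress and heat shock, 11 were higher, with a median of 0.06 (camera p 0.0178, estimated-correlation p 0.0655), and 0 passed adjusted over the list alone. Camera called this list without background correction (adjusted p 0.0377), with the 6 between-group arrays (0.0272) and without the 2 doubtful arrays (0.0385). The chaperones Hspa8, Hsp90aa1 and Hspa5 had 0.41 ± 0.15, 0.21 and 0.31 (Hspa5, printed in the upper left blocks, -0.03 with 1 loess curve per print block), and Pdia3, which forms disulfide bonds, 0.22 (0.06 without diabetic animal 3). Of 9 immediate early genes, 1 passed adjusted over the list alone, Ier3, and the median was 0.06 (camera p 0.0662, estimated-correlation p 0.191). This was the list called without diabetic animal 3 (camera adjusted p 0.0337), and it was called with the 6 between-group arrays (0.0489) and with separate channels (0.0482) too. The transcription factors Fos and Egr1 had 0.30 and 0.38, and Klf6 -0.14. The 8 heparin-binding and vascular growth factors had a median of 0.09 (0.03 without diabetic animal 3, camera p 0.0911, estimated-correlation p 0.155) and 0 passed adjusted over the list alone. Camera called that list without background correction (adjusted p 0.0483). Igfbp4, a binding protein of insulin-like growth factors, had 0.61 ± 0.19, their receptor Igf1r 0.49 ± 0.22 (0.08 without diabetic animal 3, where its level was -0.77) and Pdgfa -0.13. Igfbp4 passed the threshold over all genes without diabetic animal 2, with 0.82 and an adjusted p of 0.0375, and so did Ier3, Rfpl4 and Galnt2. Of the 6 circadian clock genes, the repressor Cry1 had 0.19, and Tef and Nr1d2, which oscillate with the clock, 0.39 and 0.28, with a list median of 0.11 (camera p 0.082, estimated-correlation p 0.149). The clock list was called without background correction (camera adjusted p 0.0487) and with the 6 between-group arrays (0.0272). Without diabetic animal 3 the median was 0.04, Tef had 0.20 and Nr1d2 0.03, and Tef, at -0.63 in that animal, differed among the diabetic animals (adjusted p 0.0176). The 15 cell cycle genes had a median of 0.05 (-0.01 without diabetic animal 3, camera p 0.0807, estimated-correlation p 0.458). Top2a at 0.08 and Ccnb2 at 0.07 were each detected on 2 arrays.

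Matrix, cytokine, Wnt and steroid genes had list medians between -0.02 and 0.09. The 18 genes of extracellular matrix and fibrosis had a median of 0.09 (-0.0055 without background correction, camera p 0.0437, estimated-correlation p 0.343). Without diabetic animal 3 the median was 0.03 with a camera p of 0.785, and without diabetic animal 1 it was 0.12 with an adjusted p of 0.00549. With the 6 between-group arrays the matrix list was called too (camera adjusted p 0.0495). The list held Dcn, the collagen-binding decorin, at 0.20 ± 0.07 (0.07 without diabetic animal 3), and Nid1 of basement membranes at -0.18 ± 0.06. The other clone of Nid1 lay on the other side. Col1a1 and the growth factor Tgfb2, both detected on 1 array, were at 0.13 and 0.17. The 5 cytokines and adhesion molecules had a median of 0.07 (-0.04 without diabetic animal 3, camera p 0.468, estimated-correlation p 0.5004). Nfkbia, the NF-kappaB inhibitor, printed in the upper left blocks, had 0.18 ± 0.05 and the neutrophil attractant Cxcl1 -0.17, while Il18 and Selp were at 0.07 and -0.06. The 9 Wnt signalling genes had a median of 0.01 (camera p 0.310, estimated-correlation p 0.351), with Apc at 0.20 (0.02 without diabetic animal 3), Dkk3 at 0.10, Ctnnb1, the beta-catenin gene, at 0.11 and Ccnd1, cyclin D1, at 0.31 (-0.11 without diabetic animal 3). The 6 genes of steroid receptors and steroid metabolism had a median of -0.02 (camera p 0.712, estimated-correlation p 0.813), with the glucocorticoid receptor Nr3c1 at 0.13 and Hsd3b1 at 0.10. In each of these 4 lists 0 genes passed adjusted over the list alone.

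Markers of hormones, sex and nearby tissues were mostly too few for a set test. Sgk1, the aldosterone-induced kinase that raises sodium uptake, had 0.99 ± 0.34 (adjusted p 0.548), but 1.57 without menopausal/diabetic animal 1 and 0.66 without menopausal/diabetic animal 3. It belongs to the 3 measured genes of the renin-angiotensin-aldosterone system, whose median was 0.09 (-0.0030 without diabetic animal 3), with Agt at -0.16 and Mme at 0.09. Of the 5 adrenal genes (camera p 0.866, estimated-correlation p 0.871), 2 passed adjusted over the list alone: Star, the cholesterol carrier of steroid-making cells, lower at -0.17 ± 0.05 (-0.03 without diabetic animal 3), and Th, the enzyme of catecholamine synthesis, which was detected on 0 of the 12 arrays and printed in the upper left blocks. Their list's median was 0.01. Lpl, the lipase of fat, at 0.29 ± 0.10 (-0.01 without menopausal/diabetic animal 2), was the single measured fat gene. Among the 4 male-biased genes the median was 0.09. Nudt19, a coenzyme A hydrolase, was at -0.20 (-0.07 without diabetic animal 3, 0.01 without menopausal/diabetic animal 2). The polyamine enzyme Odc1, which androgens raise, was at 0.30 (0.10 without diabetic animal 3). Odc1 was at 0.15, 0.11 and -0.71 in the diabetic animals, which differed in it (adjusted p 0.0136), and at 0.17, -0.10 and 0.38 in the menopausal/diabetic animals. The 2 female-biased genes were Abcc3, an organic anion pump, at -0.28 ± 0.09 (-0.09 without diabetic animal 3), which passed adjusted over the list alone, and Slc22a7, at 0.06 (-0.38 without that animal). Of the 2 sex-chromosome markers, Xist passed adjusted over the list alone, at 0.33 ± 0.09 (0.10 without menopausal/diabetic animal 2), and Eif2s3y was at -0.03. Both Xist and Lpl were printed in the upper left blocks.

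Nephron and other cell-type markers were few. The 3 proximal tubule genes had a median of 0.48, and without diabetic animal 3 of -0.09. The 2 genes of the thick ascending limb and distal tubule, Calb1, the calcium buffer calbindin, at 0.86 ± 0.38, and Wnk1, a kinase of salt transport, at 0.46 ± 0.17, had a median of 0.66, and without that animal of 0.28. Collecting duct (2 genes, with Fxyd4 at 0.24) and endothelium (3 genes, with Ehd3 at 0.21) had medians of 0.16 and 0.10, and without that animal of 0.06 and 0.02. The 3 podocyte genes had a median of 0.05, with Podxl at 0.18, and the 3 red cell genes -0.11, with Hbb-b1 at -0.23 (0.0064 without menopausal/diabetic animal 2). The 4 macrophage genes had a median of -0.02, with Lyz2 at -0.18. For antigen presentation and interferon responses 1 gene each was measured, H2-Eb1 at 0.51 ± 0.33 and Igtp at 0.32 ± 0.19, and without diabetic animal 3 these were 0.18 and 0.05. In the lists of this paragraph 0 genes passed adjusted over the list alone.

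The arrays that paired animals of 1 group ask how far mice of the same treatment differ. The genes that differed among the diabetic mice included Plin2, which coats lipid droplets, Gclc, which limits glutathione synthesis, and Lrp2, the endocytic receptor megalin, and it was mostly animal 3 that stood apart. By limma's moderated F test against the error between arrays, 146 of 9955 genes and clones differed among the 3 diabetic animals, 108 of them named, with 1305 at an unadjusted p under 0.05. Animal 3 was the farthest from the group's median for 125 of the 146. Over all 146 it was the highest of the 3 animals for 92 and the lowest for 49. The number was 31 without the array of diabetic 2 and diabetic 3, and it was 86 without that of diabetic 1 and diabetic 2, 96 without menopausal/diabetic 2 and diabetic 3, 90 without diabetic 2 and menopausal/diabetic 3, 93 without menopausal/diabetic 1 and 2, 94 without menopausal/diabetic 1 and diabetic 2, and 78 without diabetic 1 and menopausal/diabetic 2. The genes below that are outside the lists were chosen after their values were seen, from those of smallest p.

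Plin2 had the smallest p of all, with levels of -0.22, -0.53 and 2.25 in diabetic animals 1 to 3 (adjusted p 2.22e-06). Its 3 menopausal/diabetic levels lay between -0.62 and -0.43. Other genes of fat oxidation were highest in diabetic animal 3: the peroxisome factor Pex11a at 0.91, Acot2 at 0.99, Hadhb of the trifunctional protein at 0.56, the isomerase Eci1 at 1.35, the acyl-CoA-binding Dbi at 1.04 and Vnn1, a PPAR-alpha target that releases pantothenate, at 1.24. Of the 11 measured genes of fatty acid oxidation and PPAR-alpha targets, 4 differed over all genes and 7 adjusted over the list alone. Of the 15 NRF2 and oxidative stress genes, 3 differed over all genes and 6 adjusted over the list alone, with diabetic animal 3 highest for all 3: Gclc at 1.65, the metallothionein Mt2 at 1.04 and Hmox1, which breaks down heme, at 0.70. The carbonyl reductase Cbr3 was at 2.22 there, the deadenylase Noct at 1.26, the hypoxia-induced Bnip3 at 1.06, the serine synthesis enzyme Psat1 at 1.17 and S100g, calbindin D9k, at 0.83. Lcn2 differed too (adjusted p 0.0224).

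Other genes were lowest in the same animal. All 3 measured proximal tubule genes differed: Gatm, which makes the precursor of creatine, was at -1.66, Lrp2 at -1.15, and Miox, which breaks down inositol, at -0.88. The anion transporter Slc22a7 was at -1.10, Calb1 at -1.36, Odc1 at -0.71, Ccnd1 at -1.05 and Fh1, fumarate hydratase, at -0.98. H2-Eb1, a class II antigen-presenting chain, was at -1.09 and Igtp, an interferon-induced GTPase, at -0.58. Lrp2 was at 0.18 and 0.24 in diabetic animals 1 and 2 and at 0.13, 0.25 and 0.33 in the menopausal/diabetic animals.

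**Figure D3:**
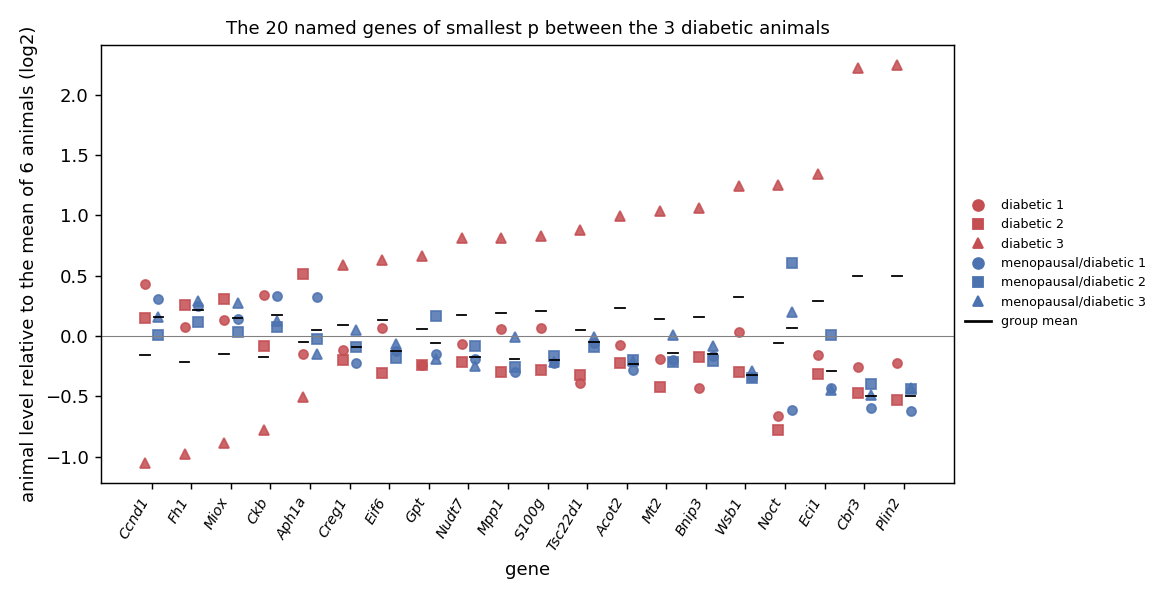
Level of each animal (log2, relative to the mean of 6 animals) for the 20 named genes of smallest p among the 3 diabetic animals; red marks diabetic and blue menopausal/diabetic animals, marker shapes the animal, bars the group means. Diabetic animal 3 is at 2.25 for Plin2 and 2.22 for Cbr3 and at -1.05 for Ccnd1.

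Among the 3 menopausal/diabetic animals the same test called 0 genes, with 511 at an unadjusted p under 0.05 and a smallest adjusted p of 0.283. Leaving out the array of diabetic 3 and menopausal/diabetic 1 gave 1. Plin2, Gclc and Lrp2 therefore differed past the threshold in the diabetic group alone, and a difference in spread between the groups was not tested. Adjusted over the list alone, 1 gene differed among these animals in each of the lists of male-biased genes, interferon-stimulated genes, the renin-angiotensin-aldosterone system and endoplasmic reticulum stress. For Sgk1 the menopausal/diabetic levels were -0.25, 0.90 and 0.84.

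Across genes, the median SD between animals of a group was 0.0879, and the median residual SD between arrays was 0.180. The error between arrays alone would give an SD between animals of 0.0823, so most of the spread between animals had the size of array error for the typical gene. Over all genes the SD of the levels was 0.193 in diabetic animal 3 and between 0.101 and 0.116 in the other 5 animals.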

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

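Print-tip loess, array weights, the sets of 10 arrays, without 2 doubtful arrays and without the 2 arrays whose titled pair ranked last, the re-matched deposited values and the names by file order were chosen after seeing the data. The cause was not tested except where fewer arrays enter. The count of genes changed, 0, became 2 with scaling between arrays and 22 with arrays as replicates (technical error in place of animal error). It became 0 to 46 with an animal left out (46 without diabetic replicate 2), and stayed 0 with any array left out and under the replicate block. Deviations of same-numbered animals from their group means correlated at -0.045 to -0.366 across genes. The array layout alone gives -0.2 there, so these values do not decide whether the animal numbers mark pairs. The count of lists, 0, became 5 without background correction, 6 with the 6 between-group arrays, 1 with separate channels, 0 to 3 with an animal left out, 1 under the replicate block, 1 with print-tip loess, 1 with array weights, 1 with the re-matched deposited values and 2 without the doubtful arrays. For the lists called, the between-group arrays and the set without the doubtful arrays left the medians at their main values. Those calls rest on a changed error and are no separate check of the differences. The fatty acid oxidation list had an adjusted p of 0.0205, 0.00916 and 0.0236 in the replicate block, print-tip and weighted cases, and 0.0014 with the between-group arrays, the lowest of its alternatives, and 0.815 at the highest; with an estimated correlation, run on all 12 arrays, its p is 0.352. Genes differing among diabetic animals, 146, became 43 without background correction, 334 with median centring, 68 with scaling, 31 to 186 with an array left out, 274 with print-tip loess, 8 without the doubtful arrays, 64 without the 2 arrays ranked last (which left genes and lists changed at 0), 56 with 10 arrays and 77 with the re-matched values; among menopausal/diabetic animals, 0 became 1 with print-tip loess and 0 to 1 with an array left out. The SD between animals and between arrays became 0.0477 and 0.0979 without background correction and 0.202 and 0.412 with the re-matched values. In the test of the 6 animals no named gene, and in camera no list, had passed its threshold, and changes of sign are counted for such values: of 112 named genes the sign differed for 11 with the re-matched values, 6 with print-tip loess, 11 of 107 without background correction, 6 of 110 with separate channels and 4 with median centring; with an animal left out it did so in 36 of 672 cases, and with an array left out in 21 of 1344. Signal over background was at most 209 and as low as 14.6 intensity units beside backgrounds of 282 to 2727, so small changes of dim genes are not resolved.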

Other observations

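The look at the ribosomal protein family and the tests of the slide position, of diabetic animal 3 and of the fatty acid oxidation list were chosen after those results were seen, and so were the upper left blocks themselves. Cytosolic ribosomal proteins, which translate all messages, made up 4 of the 10 genes ranked lowest and were then looked at as a family. Of 67 measured, 55 were lower in the menopausal/diabetic group, with a median of -0.16, and 23 of these had an unadjusted p under 0.05. The members that prompted this are among them, so no test of the family is given. The family's median level was 0.06, -0.03 and 0.21 in diabetic animals 1 to 3 and -0.09, -0.04 and -0.10 in the menopausal/diabetic animals. Over 6 other normalizations and inputs the median difference lay between -0.19 and -0.09, and without diabetic animal 3 it was -0.03.

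With arrays as replicates, which sets the groups against array error alone, 17 named genes passed the threshold. Acadm, Clu and Havcr1 were among these 17, each with an adjusted p of 0.0388. Crot, which moves shortened acyl chains out of peroxisomes, was among them too, with -0.74 and an adjusted p of 0.0386. Echs1, the short-chain hydratase, had -0.36 and 0.0378, and Dbi -0.64 and 0.0388 in that fit. With the animals as replicates the adjusted p of Crot, Echs1 and Dbi was 0.536, 0.536 and 0.610. Mdh1, the cytosolic malate dehydrogenase, had 0.39, a sign shared by 2 of its 3 clones, itself included. Of the 22 genes and clones called there, 12 also differed among the diabetic animals, Crot and Dbi with them: Crot was at 0.26, -0.06 and 0.90 there and Dbi at 0.05, -0.12 and 1.04. The levels of Echs1 were 0.05, 0.12 and 0.37 in the diabetic animals and -0.26, -0.16 and -0.11 in the menopausal/diabetic animals.

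Genes of small p crowded in the 3 upper left print blocks, Ier3, Efr3a and Slc3a2 among them, with 4.44 times the share found elsewhere. Uneven hybridisation or scanning may have contributed: other clones of such genes, printed elsewhere, kept 11.7% of the change (62 genes) against 33.8% for genes printed outside these blocks (225 genes), a ratio of 0.347 with a 95% interval of 0.118 to 0.614, which reaches above the value of 0.5 set as the bound. For a change of these genes between the groups, 58.1% of those other clones moved the same way (95% interval 44.9 to 70.5), against 74.2% for genes printed outside these blocks. The interval lies below the share set for this explanation, but the 58.1% lies above the share set against it. Genes printed outside these blocks, at 74.2%, fell short of the share set for it too. This count therefore does not decide. A change of some of them is not excluded. Over all 547 tested genes and clones of these blocks the median difference was 0.13, against -0.0054 for the 9408 elsewhere. Such a shift of the typical clone by place goes with an uneven slide, and a change of a few genes would not give it. With 1 loess curve per print block the share in these blocks fell from 31.3% to 14.6% and the median difference there from 0.13 to 0.02. Centring each block largely fixes that median in advance. Of the ranked genes printed elsewhere, Clu had 0.54 both times and Cltc 0.44 and then 0.14. How far a change of single genes contributed beside an uneven slide cannot be told here, as the genes with another clone are few.

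Diabetic animal 3 stood apart in Plin2, Cbr3, Gclc, Gatm and Lrp2. A single poor array is argued against, since the ratios of 3 of its 4 arrays correlated above 0.1 with those predicted from the other arrays, across genes. On the array with an unclear identifier, that of diabetic 2 and diabetic 3, another RNA in place of that of diabetic animal 3 is argued against too: the 5 pairs of animals with diabetic animal 3 in its dye predicted the array with correlations of 0.440 to 0.530, and every other pair with at most 0.229. Another RNA in place of that of diabetic animal 2 stays open, since the titled pair, at 0.491, ranked 2 of 30 behind the pair of menopausal/diabetic 1 and diabetic 3. Without that array 31 genes differed among the diabetic animals, and 8 without that array and the array of diabetic 3 and diabetic 1, whose correlation was -0.02. A difference of the animal itself or of its piece of cortex stays open and was not tested. Calb1 of the distal tubule, at -1.36, was low there beside the proximal tubule genes.

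The lower levels of fatty acid oxidation genes in the menopausal/diabetic group may rest on that animal for the list as a whole. Without diabetic animal 3 the list's median difference was -0.0091, inside the range of -0.05 to 0.05 set for this explanation, and it stayed below -0.1 in 5 of the 6 cases with an animal left out. The case that did not is this same value, so the count is no separate evidence. The list's median level was -0.11 and -0.18 in diabetic animals 1 and 2 and 0.41 in diabetic animal 3. In the menopausal/diabetic animals it was -0.12, -0.11 and -0.05. For the list as a whole, these values argue against a shift of this size that no single animal makes. Acadm differed from its list: it was between -0.60 and -0.54 whichever animal was left out. It was -0.63 with print-tip loess, but -0.01 with separate channels. Its adjusted p ran from 0.0722 to 0.9999 over the alternatives that kept animals as replicates and recorded it. With arrays as replicates its adjusted p was 0.0388. An effect of the VCD treatment on Acadm itself stays open.

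The 6 animals make 10 splits into 3 and 3, too few for a share under 0.05. At an adjusted p under 0.05 the real split and every other gave 0 genes (10 of 10 as large, which a real count of 0 fixes). At an unadjusted p under 0.05 the real split gave 833 genes and the highest other 1442 (2 of 10 as large), with diabetic animals 1 and 3 and menopausal/diabetic animal 2 on 1 side. For lists, the real split gave 0 and the highest other 4 (10 of 10 as large, fixed in the same way). At an unadjusted camera p under 0.05 the real split gave 4 lists and the others between 2 and 6.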
